A study of Mus musculus with 6 samples.

How the data were processed

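Polyadenylated RNA was measured by RNA sequencing in mouse embryonic stem (ES) cells that had been differentiated as hanging drops for 10 days. The cells were of the E14 line with an Nkx2-5-EmGFP transgene, a green fluorescent reporter of the cardiac transcription factor gene Nkx2-5, and were either control or knocked out for Lmna (Lmna KO). Embryoid bodies were taken apart on day 10 and cells were collected by fluorescence sorting on the reporter, per the labels' protocols. There were 3 control and 3 Lmna KO libraries. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures or clones, so p-values measure the spread between these libraries, which may be partly technical. They also do not say which part of Lmna was removed.

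One table was used. Per the submitters' processing notes, STAR, DESeq2, edgeR and the mm10 build were used; their versions, the program that counted reads, its handling of reads with several matches and its strand setting are not given in the sources used here. Per the file headers, the authors deposited raw read counts, normalised counts and RPKM per library for RefSeq transcripts, with their own fold changes and p-values. The table held 30686 transcript rows with 15680 gene symbols, and no row had a total under 21 counts. The deposited normalised values (a signal scaled per library) are headed TMM, but they equal the raw counts divided by 1 factor per library that lies within 2e-05 of DESeq2's median-of-ratios factor. The deposited RPKM values, per the file headers, were used only to work out the library totals the authors divided by, which exceed the column totals by 4955 to 7864 counts. The deposited log2 fold changes, their standard errors, the p-values and the test statistic (a score) were made by the authors, per the file headers, and were used only to describe the authors' table.

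Transcripts of 1 gene share reads, so the main analysis kept 1 transcript per gene: that with the most counts, then the longest, then the first accession. Library totals were 17690534 to 19804810 counts over all transcripts and 8487805 to 9442414 counts with 1 transcript per gene. Between 13924 and 14246 genes per library had at least 10 counts. Gapdh, an abundant housekeeping gene with many pseudogenes, had only 42 to 59 counts per library, so genes with near-identical copies elsewhere, among them ribosomal protein genes, are uncertain here. Overlapping and antisense genes are uncertain too, since the strand setting is not stated.

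Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr, TMM factors, glmQLFit and glmQLFTest with genotype as the only term, all 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit took in 14190 genes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Fold changes are Lmna KO over control. Expression is given as CPM, the counts scaled to library size with TMM factors, as mean ± SD of the 3 libraries of a group. Each adjusted p given for a gene is from this edgeR quasi-likelihood test unless another source is named.

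Before the data were examined, 39 gene lists were written, covering cardiomyocyte programmes, other cell types that an embryoid body or a loose gate could hold, the cell cycle, the nuclear envelope, signalling, metabolism and stress. Lists with at least 5 tested members, 37 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 37 lists. They were also tested with a correlation estimated per list, and with fry. Transcripts of the mitochondrial genome (0 tested members) and replication-dependent histone genes (4) were too few to test. Genes are named by a rule fixed at the same time: Lmna and Nkx2-5; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between the groups and no clone or pseudogene name; and, for each list described, up to 4 members with the smallest adjusted p. Genes named outside the rule are marked as chosen after their values were seen. Gene positions are from RefSeq on GRCm38, the assembly that mm10 names, and 14177 of the tested genes had one.

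The test was tried on simulated data first. Negative binomial counts were drawn for the real genes from the libraries' means, sizes and dispersions, with 200 genes changed. Of the 14047 genes tested there, the fit found 30.3% of 66 genes changed by 0.5 on the log2 scale, 85.1% of 67 changed by 1 and 97.0% of 67 changed by 2, and 13 of its 155 calls were genes that had not been changed. In a second simulation, with the neural list lowered, camera called that list and 0 of the others among 37 lists. Genes were drawn independently there, while the real neural and endoderm lists had estimated correlations of 0.60 and 0.66. That simulation therefore does not show how often camera calls an unchanged list in the real data.

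Alternatives fixed before the data were examined were DESeq2's size factors or upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, 2 other filters on low counts, stricter thresholds, the replicate number as a block, and leaving out each library. The longest transcript per gene and all transcripts as separate rows were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.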

Results

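Transcripts were counted in 3 control and 3 Lmna KO libraries of sorted day 10 cells, with 8487805 to 9442414 counts per library when 1 transcript was kept per gene. Lmna codes for lamins A and C, intermediate filament proteins of the nuclear lamina, and the design compares the cells collected on the Nkx2-5 reporter with and without it. Log2 CPM correlated across genes with r = 0.990 to 0.992 between control libraries, 0.978 to 0.988 between Lmna KO libraries and 0.912 to 0.958 between the groups. No 2 libraries agreed within sampling noise (chi-square per degree of freedom of at least 2.52 for each pair). Lmna KO 1 lay farthest from the controls and Lmna KO 3 nearest.

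The targeted gene was low in every Lmna KO library. Lmna (NM_001002011, chromosome 3, 88481148 to 88509932 on GRCm38) had 66.3 ± 7.53 CPM in control and 4.15 ± 0.586 in Lmna KO cells, 15.9-fold lower (log2 fold change −3.99, SE 0.14, edgeR adjusted p = 7.71e-08). Its raw counts were 593, 522 and 663 in the controls and 37, 29 and 43 in the Lmna KO libraries. An exact permutation test of the log2 CPM gave p = 0.1 (two-sided), the smallest that 3 against 3 libraries allow. Nkx2-5 (chromosome 17, 26838664 to 26844988), the gene behind the reporter used for the sort, had 64.1 ± 6.11 CPM in control and 186 ± 27.8 in Lmna KO cells (2.90-fold, log2 fold change 1.54, SE 0.12, edgeR adjusted p = 6.13e-06); because the sort used this gene's reporter, its level is tied to how the cells were chosen.

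Heart muscle genes rose and neural, Hox and cell-cycle genes fell in Lmna KO cells, with 3384 genes higher and 3147 lower of 14190 tested by edgeR (46.0%). Of these, 1198 rose and 633 fell by more than 1 on the log2 scale. The values of the 2 groups did not overlap for 8208 genes (57.8%), against 10% by chance. Of 37 gene lists tested, camera called 16 higher and 7 lower. With an estimated correlation in place of the preset one it called 0 lists at adjusted p (6 at an unadjusted p under 0.05), so no list call held in that test, while fry, which does not compare a list with other genes, called 26.

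**Figure D1:**
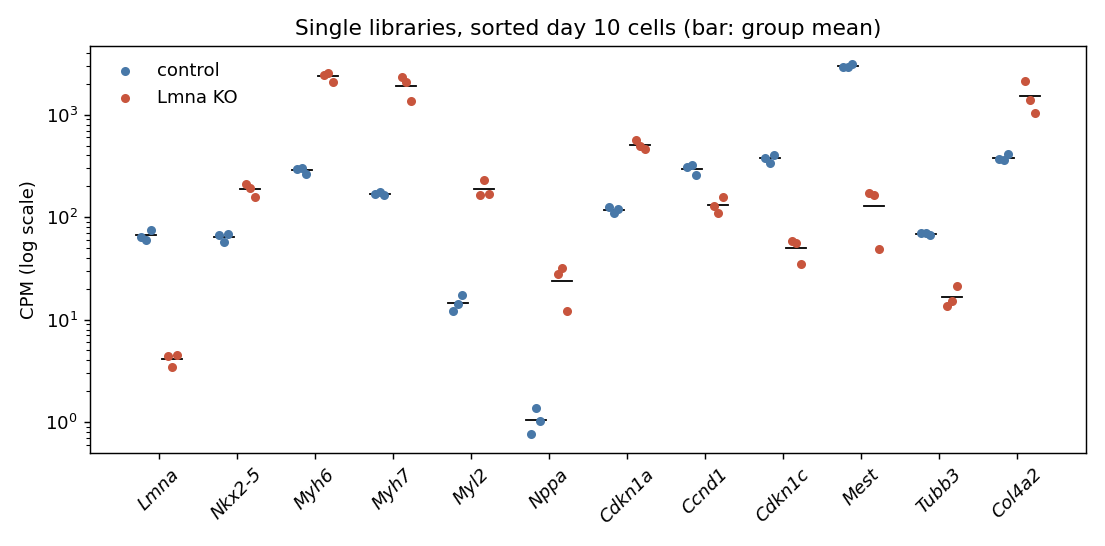
Expression (CPM, log scale) of 12 genes in each library, control in blue and Lmna KO in red, with the group mean as a bar. Lmna lies near 66.3 CPM in controls and near 4.15 CPM in Lmna KO libraries, and Myh6 and Myl2 show higher values in all 3 Lmna KO libraries than in any control.

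The largest rises were in a few cardiac genes and several genes of other kinds. Nppb and Nppa, which code for the natriuretic peptides secreted by heart muscle cells, rose 31.2-fold and 22.6-fold, Nppa from 1.05 ± 0.307 to 24.0 ± 10.5 CPM. Mb (myoglobin) rose 17.2-fold, Fsd2 14.9-fold, Obscn (obscurin, a giant sarcomere protein) 14.8-fold and Myl2 (the ventricular regulatory light chain) 12.9-fold, from 14.5 ± 2.56 to 187 ± 38.1 CPM (edgeR adjusted p = 3.31e-07). Srgn (the core protein of a proteoglycan of secretory granules) had the highest fold change of those named, 67.3-fold (log2 fold change 6.07, SE 0.68, edgeR adjusted p = 8.58e-05), and differed widely between the Lmna KO libraries, with 108, 44.8 and 23.8 CPM against at most 0.916 in a control. Aqp8 (a water channel) rose 22.9-fold, Foxe1 (a forkhead factor of the thyroid and foregut) 18.8-fold and Cemip (a hyaluronan-degrading protein) 18.0-fold. Without Lmna KO 1 the log2 fold change of Srgn was 5.29 and that of Aqp8 3.85 in place of 4.52, and without control 3 that of Nppb was 5.72 in place of 4.96.

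The largest falls held neural and patterning genes and 2 imprinted genes. Mest, an imprinted gene expressed from the paternal allele, fell from 2975 ± 108 to 128 ± 68.7 CPM, 23.2-fold (log2 fold change −4.54, SE 0.39, edgeR adjusted p = 1.38e-05). Phlda2, a maternally expressed imprinted gene, fell 13.3-fold, from 101 ± 8.98 to 7.57 ± 1.36 CPM. Hoxb1, Zic1, Hes5, Cnpy1, En2, Pou3f2 and Dcc fell 17.1-fold, 17.0-fold, 16.9-fold, 16.9-fold, 13.1-fold, 12.2-fold and 11.3-fold. Zic1, En2 and Pou3f2 are transcription factors of the developing nervous system, Hes5 is a target of Notch in neural progenitors, and Dcc is a netrin receptor of growing axons. Without Lmna KO 3 the log2 fold changes of the genes just listed, from Hoxb1 to Dcc, were all larger in size, and 4 moved by over 1.5 times as a fold: they were −5.64 for Zic1, −4.75 for Hoxb1, −4.74 for Hes5 and −4.55 for Pou3f2, against −4.08, −4.10, −4.08 and −3.61 with it.

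All 35 tested genes of the contractile apparatus rose, with a median log2 fold change of 2.94 and a range of 0.65 to 3.88, and all 35 also passed when adjusted over the list alone (camera adjusted p = 1.12e-22; adjusted p = 0.276 with an estimated correlation). Myh6, the alpha myosin heavy chain, rose from 286 ± 22.0 to 2373 ± 255 CPM (8.29-fold, log2 fold change 3.05, SE 0.10, edgeR adjusted p = 7.33e-08). Myl3 rose 7.94-fold, Myom1 8.16-fold and Xirp1 10.4-fold. The median of the list against the control mean was 2.87, 3.07 and 2.47 in Lmna KO 1, 2 and 3. In the same 3 libraries the neural list had medians of −2.77, −2.08 and −1.35 and the endoderm list 2.17, 1.52 and 0.76.

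Genes of calcium handling and ion channels also rose, 23 of 36 (3 fell, 10 did not pass; the same numbers adjusted over the list alone), with a median log2 fold change of 1.43 (camera adjusted p = 1.28e-07; adjusted p = 0.113 with an estimated correlation). Ryr2, the calcium release channel of the sarcoplasmic reticulum, rose 5.74-fold, from 49.7 ± 1.91 to 285 ± 32.7 CPM. The sodium-calcium exchanger gene Slc8a1 rose 6.51-fold, and the calcium channel genes Cacna1h and Cacnb2 rose 3.88-fold and 5.17-fold. Among 32 cardiac transcription factors 19 rose, 3 fell and 10 did not pass (21 and 4 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.000203; adjusted p = 0.352 with an estimated correlation). Smyd1, Hopx and Myocd rose 4.89-fold, 4.6-fold and 4.95-fold, while Tbx3, a factor of the conduction system, fell 2.74-fold, from 129 ± 1.76 to 47.1 ± 1.48 CPM.

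Both chamber lists rose. Of 9 ventricular markers 8 rose and 1 fell, with a median log2 fold change of 2.35 (camera adjusted p = 0.000246; adjusted p = 0.264 with an estimated correlation). Irx4, a ventricular homeobox factor, rose 6.19-fold and Lrrc10 5.09-fold. Of 12 atrial markers 8 rose, 2 fell and 2 did not pass, with a median of 1.17 (camera adjusted p = 0.00527; adjusted p = 0.264 with an estimated correlation). The atrial light chain genes Myl7 and Myl4 rose 6.99-fold, from 127 ± 8.74 to 887 ± 165 CPM, and 6.11-fold. Dkk3 rose 1.90-fold. The medians in Lmna KO 1, 2 and 3 were 1.47, 1.14 and 0.87 for the atrial list, in the order of the neural and endoderm markers, and 2.12, 2.53 and 1.86 for the ventricular list, in another order. Adjusted over the list alone, both chamber lists gave the same numbers. Of 13 genes of the cardiac stress response 12 rose and 0 fell, also adjusted over the list alone, with a median of 2.46 (camera adjusted p = 2.76e-07; adjusted p = 0.352 with an estimated correlation). Myh7, the beta myosin heavy chain, rose 11.3-fold, from 170 ± 6.43 to 1922 ± 490 CPM, Ankrd1 7.67-fold and Hspb7 5.52-fold. The contractile, chamber and stress lists share members, 8 of the 13 stress genes being held by another list. The contractile list had a median of 2.94, so the rise of the stress list cannot be told apart from that of heart muscle genes in general. It does not by itself show a stress response. Pacemaker and conduction markers went both ways (4 rose, 4 fell, 7 did not pass, the same adjusted over the list alone; camera adjusted p = 0.816): Hcn4, the pacemaker channel gene, rose 3.31-fold and Igfbp5 2.87-fold, and Cntn2 fell 7.49-fold.

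**Figure D2:**
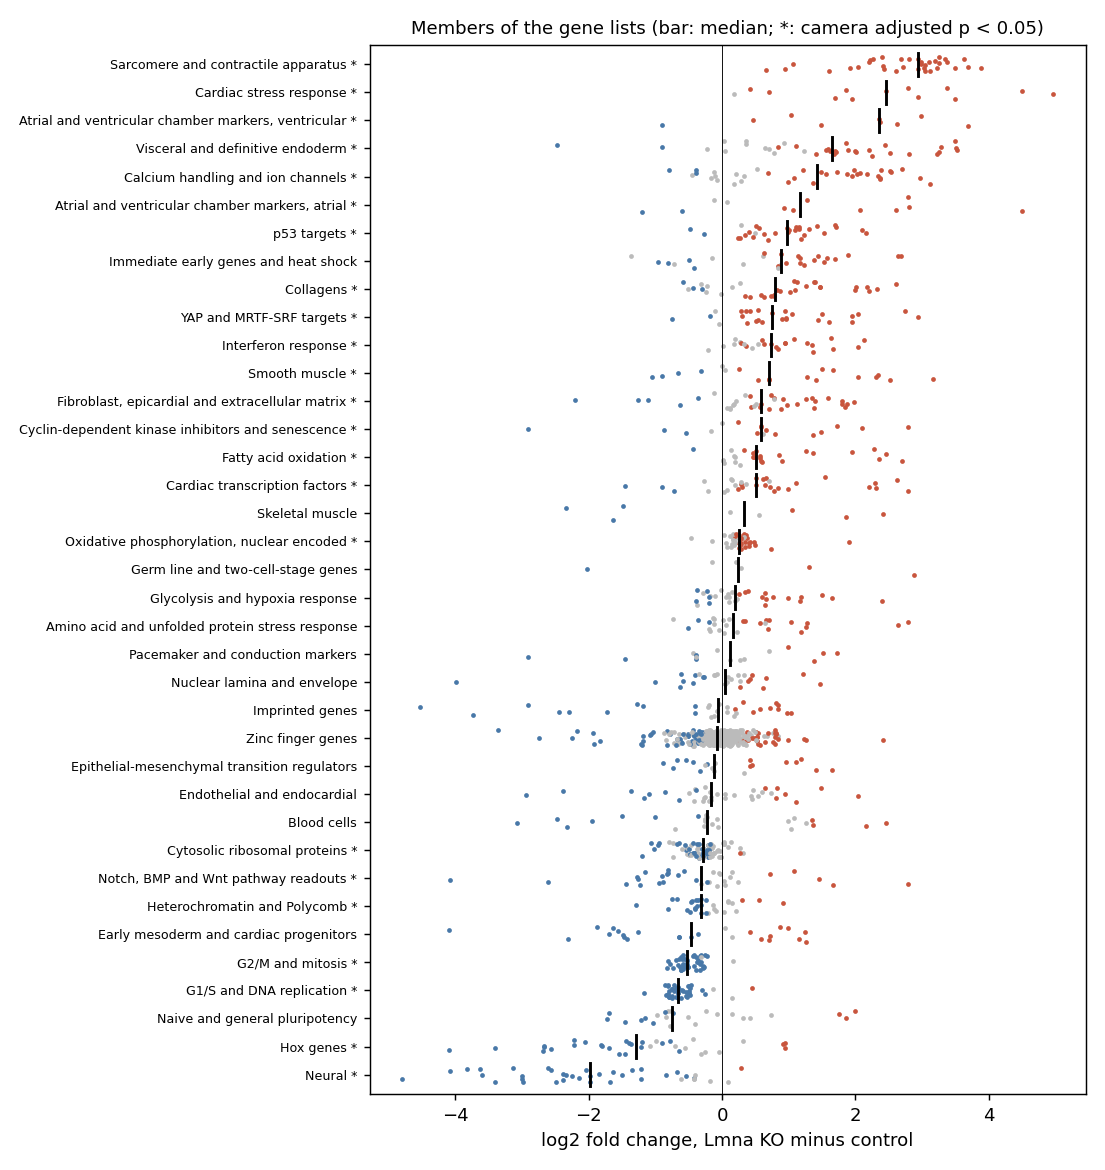
Log2 fold change (Lmna KO minus control) of each tested member of the 37 lists, as points, red where a gene rose past the threshold, blue where it fell and grey where it did not pass, with the list median as a bar and an asterisk on lists that camera called. The contractile list has the highest median, 2.94, and the neural list the lowest, −1.99.

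Cell-cycle genes fell by small amounts in nearly every case. Of 44 genes of the G1/S transition and DNA replication 41 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of −0.66 (camera adjusted p = 1.32e-11; adjusted p = 0.354 with an estimated correlation). Ccnd1 (cyclin D1) fell 2.26-fold, from 298 ± 33.9 to 132 ± 24.0 CPM, Mcm3, which codes for a subunit of the replicative helicase, 1.69-fold, the replication factor gene Mcm10 1.80-fold, and Chaf1a 1.68-fold. Of 45 genes of G2/M and mitosis 43 fell and 0 rose (43 and 1 adjusted over the list alone), with a median of −0.52 (camera adjusted p = 3.34e-11; adjusted p = 0.352 with an estimated correlation). Plk1, a mitotic kinase gene, fell 1.78-fold and Bub1b, a checkpoint kinase gene, 1.67-fold. Kif20a fell 1.51-fold and Racgap1 1.48-fold. The medians of the G1/S list were −0.82, −0.66 and −0.46 in Lmna KO 1, 2 and 3. Those of the G2/M list were −0.52, −0.51 and −0.37, with Lmna KO 1 and 2 nearly alike. Lmna KO 3 lay nearest to the controls in both, as for the neural (−2.77, −2.08 and −1.35) and endoderm markers (2.17, 1.52 and 0.76). Across all genes too, Lmna KO 1 lay farthest from the controls and Lmna KO 3 nearest. A shared order therefore does not by itself link lists.

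Targets of p53 rose, 26 of 30 (2 fell; 28 and 2 adjusted over the list alone), with a median log2 fold change of 0.98 (camera adjusted p = 9.07e-10; adjusted p = 0.112 with an estimated correlation). The medians of this list were alike in the Lmna KO libraries, at 0.97, 0.91 and 0.87. Cdkn1a, the gene of the CDK inhibitor p21, rose from 118 ± 8.0 to 510 ± 51.9 CPM (4.31-fold, log2 fold change 2.11, SE 0.09, edgeR adjusted p = 3.00e-07), Ccng1 2.46-fold, Eda2r 3.28-fold and Phlda3 2.67-fold. In the list of CDK inhibitors and senescence genes 11 of 17 rose and 3 fell, also adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.0328; adjusted p = 0.430 with an estimated correlation). Its medians were 0.75, 0.59 and 0.35 in Lmna KO 1, 2 and 3, in the same order as the neural and endoderm markers. Without Lmna KO 3 the camera adjusted p was 0.0510 (over all settings the adjusted p ran from 0.00546 by fry to 0.430 by camera with an estimated correlation), although the 2 libraries that remain have the larger medians. Igfbp7 and Cdkn2b rose 3.30-fold and 2.58-fold, and Cdkn1c, an imprinted CDK inhibitor gene, fell 7.51-fold, from 375 ± 32.8 to 50.1 ± 13.0 CPM.

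Neural markers fell, 32 of 39 (1 rose, 6 did not pass; 33 fell and 1 rose adjusted over the list alone), with a median log2 fold change of −1.99 (camera adjusted p = 5.00e-10; adjusted p = 0.388 with an estimated correlation). Tubb3, the neuronal beta tubulin gene, fell from 69.0 ± 2.14 to 16.6 ± 3.94 CPM (4.13-fold), the neurofilament genes Nefm and Nefl 8.03-fold and 3.97-fold, and Fabp7, a gene of radial glia, 10.7-fold. Of 34 Hox genes 22 fell and 3 rose (23 and 3 adjusted over the list alone), with a median of −1.29 (camera adjusted p = 9.04e-08; adjusted p = 0.112 with an estimated correlation). Hoxb2, Hoxb3 and Hoxb5 fell 3.54-fold, 2.72-fold and 6.38-fold, next to Hoxb1 in the same cluster. Readouts of Notch, BMP and Wnt signalling fell in 17 of 33 cases and rose in 5 (19 and 5 adjusted over the list alone), with a median of −0.31 (camera adjusted p = 0.00889; adjusted p = 0.352 with an estimated correlation). The Wnt readouts Nkd1 and Lef1 fell 1.76-fold and 2.35-fold, and Bmp7, a ligand gene, rose 3.18-fold.

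Endoderm markers moved the other way. Of 36 tested 24 rose and 2 fell (26 and 2 adjusted over the list alone), with a median log2 fold change of 1.65 (camera adjusted p = 2.63e-05; adjusted p = 0.528 with an estimated correlation). Lama1 rose 6.98-fold, from 124 ± 4.14 to 867 ± 469 CPM, Thbd 9.34-fold, Col4a2 4.02-fold and Cldn6 3.06-fold. The most abundant members, Col4a1, Sparc, Col4a2 and Lamb1, are basement membrane genes that other cells make too. Of the 36 members 8 stand in another list, and the other 28 had a median of 1.70. Afp, the alpha-fetoprotein gene of visceral endoderm, chosen after its values were seen, had 14.8, 12.9 and 30.6 CPM in the controls and 180, 106 and 48.0 CPM in Lmna KO 1, 2 and 3. The endoderm and neural lists both differed between the Lmna KO libraries, Lmna KO 1 being farthest from the controls and Lmna KO 3 nearest in each.

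**Figure D3:**
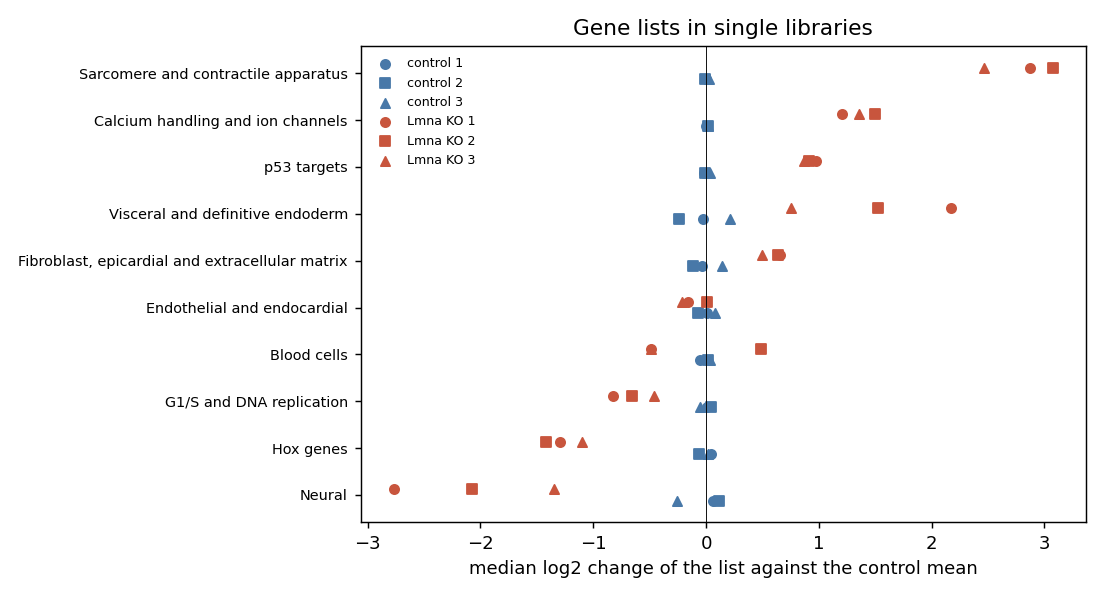
Median log2 change against the control mean of 10 gene lists in each library, control in blue and Lmna KO in red, with the replicate number as the marker shape. The endoderm medians of 2.17, 1.52 and 0.76 and the neural medians of −2.77, −2.08 and −1.35 lie farther apart between Lmna KO libraries than the p53 target medians of 0.97, 0.91 and 0.87.

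Endothelial and blood markers went both ways. Of 36 endothelial and endocardial genes 7 rose, 8 fell and 21 did not pass (6 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.377). Those that fell included early haemato-endothelial regulators: Etv2 fell 7.72-fold, Tal1 5.21-fold, from 36.1 ± 1.54 to 6.94 ± 1.97 CPM, Aplnr 2.58-fold and Kdr 1.56-fold. Of 24 blood genes 4 rose, 7 fell and 13 did not pass (5 and 7 adjusted over the list alone; camera adjusted p = 0.377). The macrophage genes Csf1r and Cd68 rose 5.51-fold and 2.59-fold, and Gata1, the erythroid factor, fell 5.01-fold. The medians of the blood list were −0.49, 0.49 and −0.48 in Lmna KO 1, 2 and 3, so Lmna KO 2 had the opposite sign. Among early mesoderm and cardiac progenitor genes 9 of 25 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 0.410). Fgf8 and Isl1, genes of the second heart field, rose 2.38-fold and 2.00-fold, while Hoxb1 and Kdr, also in this list, fell 17.1-fold and 1.56-fold.

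More genes rose than fell in the lists of smooth muscle, of YAP and MRTF-SRF targets, of collagens and of fibroblast and matrix genes. Of 19 smooth muscle genes 13 rose and 4 fell, also adjusted over the list alone, with a median log2 fold change of 0.71 (camera adjusted p = 0.00167; adjusted p = 0.430 with an estimated correlation). Synpo2, Lmod1, Actg2 and Mcam rose 5.05-fold, 8.95-fold, 5.74-fold and 2.42-fold. Targets of YAP and of MRTF-SRF, which respond to mechanical tension and actin polymerisation, rose in 23 of 27 cases and fell in 2, also adjusted over the list alone, with a median of 0.75 (camera adjusted p = 7.79e-07; adjusted p = 0.352 with an estimated correlation). Acta2, smooth muscle actin, rose 4.11-fold, from 1098 ± 194 to 4509 ± 1120 CPM, Myl9 3.05-fold and Lats2 1.87-fold. Another list holds 10 of these 27 genes. Of 34 collagen genes 24 rose and 3 fell (24 and 5 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 2.63e-05; adjusted p = 0.354 with an estimated correlation). Col12a1, Col8a1, Col8a2 and Col11a1 rose 4.51-fold, 5.00-fold, 4.62-fold and 2.14-fold. Fibroblast, epicardial and matrix genes rose in 21 of 37 cases and fell in 5 (23 and 5 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.000340; adjusted p = 0.453 with an estimated correlation). Postn (periostin) rose 3.50-fold, Col1a1 2.64-fold and Timp3 2.55-fold, and Thy1 fell 4.61-fold. Another list holds 10 of the 34 collagen and 12 of the 37 fibroblast and matrix genes. In Lmna KO 1, 2 and 3 the medians were 0.95, 0.92 and 0.67 for collagens, 0.66, 0.64 and 0.49 for fibroblast and matrix genes and 0.85, 0.80 and 0.63 for smooth muscle, in the same order as the endoderm markers (2.17, 1.52 and 0.76). Those of the YAP and MRTF-SRF targets were 0.87, 0.68 and 0.69, in another order.

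Genes of mitochondrial energy metabolism rose. Fatty acid oxidation genes rose in 18 of 27 cases and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 1.67e-06; adjusted p = 0.352 with an estimated correlation). Cpt1b, the muscle form of the carnitine transferase that admits fatty acids to mitochondria, rose 4.87-fold. Ppargc1a, a coactivator of mitochondrial biogenesis, rose 5.52-fold, Acadvl 2.56-fold and Lpl 1.87-fold. Of 44 nuclear genes of oxidative phosphorylation 25 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of only 0.26 (camera adjusted p = 1.62e-05; adjusted p = 0.430 with an estimated correlation). Cox7a1, the muscle isoform of a cytochrome oxidase subunit, rose 3.73-fold, while Ndufb10, Ndufs7 and Atp5o rose 1.39-fold, 1.34-fold and 1.33-fold. The medians in Lmna KO 1, 2 and 3 were 0.62, 0.55 and 0.36 for fatty acid oxidation and 0.31, 0.29 and 0.18 for oxidative phosphorylation. This is the order of the neural and endoderm markers, though Lmna KO 1 and 2 were nearly alike for oxidative phosphorylation.

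Interferon response genes rose in 17 of 25 cases and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 1.45e-06; adjusted p = 0.352 with an estimated correlation). Tap1, a peptide transporter of antigen presentation, rose 3.19-fold, B2m 1.78-fold, from 91.1 ± 8.29 to 162 ± 16.6 CPM, and the antiviral genes Rsad2 and Ifit1 4.10-fold and 3.11-fold. The medians of this list were 0.67, 0.67 and 0.87 in Lmna KO 1, 2 and 3, so Lmna KO 3 lay farthest from the controls here.

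Of 30 heterochromatin and Polycomb genes 18 fell and 3 rose, also adjusted over the list alone, with a median log2 fold change of −0.31 (camera adjusted p = 0.00468; adjusted p = 0.352 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase gene, fell 2.45-fold, the Polycomb genes Ezh2 and Cbx2 1.6-fold and 1.69-fold, and Cbx4 rose 1.88-fold. The medians of this list were −0.37, −0.30 and −0.18 in Lmna KO 1, 2 and 3, again in the order of the neural and endoderm markers. The Notch, BMP and Wnt list had this order too (−0.37, −0.33 and −0.31), as did the p53 targets by small steps (0.97, 0.91 and 0.87). Some called lists did not. Lmna KO 2 lay farthest from the controls for Hox genes (−1.29, −1.42 and −1.10) and cardiac transcription factors (0.53, 0.61 and 0.42). The same held for the cardiac stress response (2.52, 2.65 and 1.99), calcium handling and ribosomal protein lists. Of 29 genes of the nuclear lamina and envelope 8 rose and 9 fell, Lmna among them (10 and 10 adjusted over the list alone; camera adjusted p = 0.893, the median of 0.04 and the mean of −0.08 differing in sign). Tmem38a and Syne1 rose 2.76-fold and 2.31-fold and Tmem43 1.58-fold. Cytosolic ribosomal protein genes fell in 32 of 79 cases and rose in 1 (31 and 1 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 7.44e-07; adjusted p = 0.112 with an estimated correlation). Rplp0, Rpl7l1, Rpl41 and Rpl7a fell 1.40-fold, 1.35-fold, 1.33-fold and 1.29-fold; these genes have many processed copies in the genome, so their counts are uncertain.

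Imprinted genes changed in both directions, 10 of 30 up and 10 down (10 and 12 adjusted over the list alone), with no call as a list (camera adjusted p = 0.568). Besides Mest, Phlda2 and Cdkn1c, Peg10, an imprinted gene derived from a retrotransposon, fell 2.28-fold, from 3334 ± 168 to 1461 ± 119 CPM. Pluripotency genes fell in 8 of 24 cases and rose in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0625). Lin28a fell 2.23-fold, from 430 ± 5.08 to 192 ± 56.0 CPM, while Klf2 and Klf5 rose 3.64-fold and 3.37-fold. The medians of the pluripotency list differed between libraries, at −0.60, −1.07 and −0.17 in Lmna KO 1, 2 and 3.

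Per the authors' deposited table, 5932 transcripts of 2976 genes were higher and 5644 transcripts of 2960 genes lower in Lmna KO cells at an adjusted p under 0.05. For Lmna the authors' deposited table gives a log2 fold change of −4.01 with a standard error of 0.19 and an adjusted p of 9.47e-95. Among the tested genes, 5661 passed both in the authors' deposited table (5725 genes) and in the edgeR fit (6531 genes), all of them with the same direction.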

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

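The longest transcript per gene and all transcripts as rows were settings chosen after seeing the data. Of the 3384 genes higher and 3147 lower in Lmna KO cells, counts stayed within 1.5 times under other scaling factors, DESeq2, limma-voom, other filters and either choice of transcripts, and no gene called in the main edgeR fit was called with the opposite sign in the other fits with 1 transcript per gene. At an adjusted p under 0.01, 1952 genes were lower, and with a log2 fold change beyond 1 as well as an adjusted p under 0.05, 1198 were higher and 633 lower, because these thresholds are stricter by construction; likewise 3392 transcripts passed in the authors' deposited table with a log2 fold change beyond 1, against 11576 without it. DESeq2's Wald test called 2924 genes higher and 2781 lower. Leaving out 1 library gave 2648 to 3532 genes higher, 2296 to 3397 lower, 23 to 26 lists and a log2 fold change of Lmna of −4.07 to −3.88. Of the 23 lists called by camera, 0 passed with an estimated correlation (smallest adjusted p = 0.112). The p53 and ribosomal protein lists had estimates of 0.012 and 0.013, near the preset 0.01. Their camera adjusted p still went from 9.07e-10 and 7.44e-07 to 0.112. The size of the correlation therefore does not account for the loss of these calls. An adjusted p with an estimated correlation thus does not measure the correlation between genes alone, and the cause was not tested further. Without Lmna KO 3 the list of CDK inhibitors and senescence genes had a camera adjusted p of 0.0510 (over all settings 0.00546 with fry to 0.430 with an estimated correlation); 1 other setting, the estimated correlation, also ended its call. Lists without a call passed in some of the other settings: pluripotency in 6, immediate early and heat shock genes in 3, glycolysis and hypoxia in 2, and the epithelial-mesenchymal, amino acid stress, blood and zinc finger lists in 1 each. The other 153 named genes kept their direction and their side of the threshold in every setting, and for 11 named genes leaving out 1 library moved the fold by over 1.5 times. Another scaling shifted the median gene by at most 0.013 in size on the log2 scale (−0.013 with upper-quartile factors).

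With the replicate number as a block, 3097 genes were higher and 2843 lower (5858 of the main calls kept), 24 lists passed and the log2 fold change of Lmna was −4.0. Libraries with the same number did not deviate together: the correlations of their deviations from the group means were −0.03, 0.08 and −0.21, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries.

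On counts simulated at the depth and spread of these 3 Lmna KO and 3 control libraries, 30.3% of genes changed by 0.5 on the log2 scale were found, against 97.0% of those changed by 2. Only 200 genes were changed there, so these shares do not carry over to the real comparison, where far more genes passed.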

Other observations

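The tests of cell shares, of Y-linked genes and of the spread of imprinted genes between libraries were chosen only after the values they measure were seen; those of expression level, of neighbouring genes and of other splits were written before.

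Several stress and metabolic lists moved in part without a call by camera in the main setting. Of 27 immediate early and heat shock genes 16 rose and 4 fell (18 and 4 adjusted over the list alone; median log2 fold change 0.89, camera adjusted p = 0.0659). Lmna KO 1 stood apart in this list, with a median of 1.44 against 0.53 in both Lmna KO 2 and Lmna KO 3 and −0.29 to 0.23 in the controls. Nr4a1 and Hspb1 rose 3.69-fold and 3.25-fold, and Myc and Hsph1 fell 1.75-fold and 1.94-fold. Glycolysis and hypoxia genes rose in 14 of 31 cases and fell in 5, also adjusted over the list alone (camera adjusted p = 0.0913), with Hk1 (hexokinase 1) 3.15-fold, Car9 5.28-fold, P4ha2 2.82-fold and Pfkp 1.57-fold higher. Among 28 genes of the amino acid and unfolded protein responses 12 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.142). Atf3, Trib3, Cebpb and Herpud1 rose 6.26-fold, 2.42-fold, 2.39-fold and 2.05-fold.

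Regulators of the epithelial-mesenchymal transition went both ways, 8 of 20 up and 7 down, also adjusted over the list alone (camera adjusted p = 0.713, with a median of −0.12 and a mean of 0.17). Esrp1, an epithelial splicing factor gene, rose 3.14-fold, Tgfb2 1.94-fold and Tgfbr2 2.15-fold, and Twist1 fell 1.86-fold. Of 8 skeletal muscle genes 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.713): Acta1 and Tnnt1, which heart muscle also makes, rose 3.64-fold and 5.31-fold, and Tnnt3 and Pax3 fell 2.79-fold and 5.05-fold, Pax3 with a log2 fold change of −3.27 without Lmna KO 3 against −2.34 with it. Of 6 germ line and two-cell-stage genes Prdm1 rose 2.46-fold, Rhox6 rose 7.38-fold and Sycp3 fell 4.07-fold, the same adjusted over the list alone (camera adjusted p = 0.606); the log2 fold change of Rhox6, 2.88, was 2.30 without control 1 and 4.52 without control 2. Of 321 zinc finger genes 27 rose and 52 fell (16 and 34 adjusted over the list alone; camera adjusted p = 0.119). Zfp711, Zfp423 and Zfp41 fell 2.32-fold, 2.05-fold and 2.27-fold. Of 4 histone genes H1f2 and H2bc4 rose 2.68-fold and 3.21-fold, and the list was too short to test.

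Contractile genes were higher and neural genes lower in Lmna KO cells, which raises the question of the mixture of cells in the sort. A smaller share of non-cardiac cells as the whole cause would lower endoderm and neural markers alike, if only non-cardiac cells make them. The endoderm median was instead 1.65 (95% bootstrap interval over genes 1.08 to 1.99), against a neural median of −1.99 (−2.39 to −1.36). These intervals treat genes as independent, while the estimated correlations were 0.66 and 0.60, and they do not measure the spread between libraries. In Lmna KO 1, 2 and 3 the endoderm medians were 2.17, 1.52 and 0.76 and the neural medians −2.77, −2.08 and −1.35, with opposite signs in each library. The most abundant endoderm members are basement membrane genes that other cells make too, so the list does not read endoderm cells alone. The 28 members in no other list had a median of 1.70, but which cells make them is not known here. This comparison therefore cannot exclude a smaller non-cardiac share. A larger share of cardiomyocytes may still account for part of the contractile rise: the log2 fold changes of the 35 contractile genes had an SD of 0.77 against a median standard error of 0.14, but how much of each gene other cells make is not known here, so that share and an effect of the genotype within cardiomyocytes cannot be told apart. A change in endoderm cells within the sort stays open and untested, as does the genotype.

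Transcripts of the Y chromosome were low in Lmna KO 1 and Lmna KO 2 but not in Lmna KO 3. Ddx3y had 31.0 to 34.0 CPM in the controls and 4.05, 8.51 and 33.5 CPM in Lmna KO 1, 2 and 3. Uty and Eif2s3y, the other Y-linked genes tested, were likewise lower in Lmna KO 1 and 2 than in any other library. The falls were uneven. Against the control mean, the log2 changes in Lmna KO 1 and 2 were −2.94 and −1.91 for Ddx3y and −2.51 and −2.08 for Uty. Those of Eif2s3y were only −1.61 and −1.27. In Lmna KO 3 Eif2s3y had 81.6 CPM, against 49.3 to 61.7 CPM in the controls. Loss of the Y chromosome in part of the cells of these 2 libraries is a candidate explanation: all 3 genes lay at least 1 log2 unit below the control mean in both (the highest was −1.27), while no autosome or X had a median beyond 0.153 in size in a Lmna KO library. A swap of Lmna KO 3 with a control is argued against by its Lmna level, −3.79 on the log2 scale against the control mean. A part of the genotype in this was not tested, and the labels do not say whether the Lmna KO libraries came from 1 clone.

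Imprinted genes changed more than other genes. The median absolute log2 fold change of 29 imprinted genes was 0.58, at percentile 99.97 of 10000 random lists matched on mean expression (median 0.27). Expression level alone does not account for this if genes are taken as independent. The draws took genes singly, while Phlda2 and Cdkn1c, close together on chromosome 7, both fell, so the percentile may be too high. The median range of the imprinted genes over the Lmna KO libraries was 0.35, against 0.28 in random lists matched on both mean expression and the size of the change (percentile 93.3). This range does not depend on which library stands apart, so it cannot speak for or against a separate culture history of Lmna KO 3. Chosen after their values were seen, H19 had 205, 332 and 27.2 CPM and Mest 171, 165 and 49.0 CPM in Lmna KO 1, 2 and 3, against at least 923 and 2897 CPM in the controls, so both were lowest in Lmna KO 3. Whether the genotype or the history of the cells changed them was not tested, and allele-specific reads were not analysed here.

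Neighbouring genes changed together, though weakly. Over 12412 pairs of adjacent, non-overlapping genes Spearman's rho of the log2 fold changes was 0.097, above the highest of 1000 shuffles within chromosomes (0.040). It was 0.086 over 11904 pairs whose names differ in the first 3 letters, so tandem genes with like names are not the whole cause. Related neighbours with unlike names were not removed. A regional change along the chromosome may be behind this, but neighbours that share expression in 1 cell type would give such a correlation in any comparison of unlike cells. Maps of lamina contacts were not analysed here.

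For the genes higher and the genes lower in Lmna KO cells, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many calls: 3384 higher and 3147 lower, against a highest of 0 in any other split with edgeR (370 genes at most at an unadjusted p under 0.05). With 10 splits no share under 0.05 can be reached. Each other split also put control and Lmna KO libraries together in both groups. The difference between control and Lmna KO then widens the spread within groups, so the 0 calls there do not measure what chance would give.

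In the authors' deposited table, Kalrn alone has transcripts past the threshold in both directions: NM_177357 with a log2 fold change of −0.30 (adjusted p = 0.0212) and NM_001164268 with 0.62 (adjusted p = 0.00164).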
